A study of Mus musculus with 2 samples.

How the data were processed

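Accessible chromatin was mapped by DNaseI sequencing in 1 lymphoma, called T6, from the Eμ-myc mouse. In this model the Myc oncogene is driven in B cells by the enhancer of the immunoglobulin heavy chain locus. The tumour lacked Arf, which restrains Mdm2 and so protects p53, and carried intact Trp53. Per the labels' protocols, the cells were untreated, were pressed out of lymph nodes and were not purified further, so that other lymph node cells could be present. DNaseI cuts DNA most readily where nucleosomes are absent or displaced, and stretches with many cut ends are called as DNaseI sites. The series has 2 libraries, the DNaseI library and an input library of the same tumour. Only the DNaseI library's list of sites was analysed here; the input library was not analysed here.

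Per the submitters' processing notes, the tools were BWA 0.6.2 and SAMtools, and the genome build was mm9. The peak caller, its threshold, the filters and the use of the input are not given in the sources used here. The deposited list has 3 columns, the chromosome, start and end of each site, without a header. It gives no score, height, read count or p-value, so the depth of the library and the strength of a site are unknown, and no site can be ranked by signal. Width was the measure of size that the list allowed. Width depends on the caller's settings and on depth as well as on the chromatin. All coordinates below are mm9 and are counted from 1. There was 1 library and no replicate, so no test between groups was possible and no p-value is given. Intervals for counts and shares are exact Poisson and exact (Clopper-Pearson) binomial intervals at 95%, and those for medians come from order statistics. They cover counting error only, and neighbouring sites are not independent, so that the true uncertainty is larger. Intervals for a ratio to the median of the other autosomes treat that median as fixed, so the spread between autosomes is not in them.

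Gaps were measured between the end of a site and the start of the next on the same chromosome. Density per chromosome was the number of sites divided by the distance from the first to the last site, because lengths of the mm9 chromosomes were not used here. The number of protein-coding genes per chromosome was counted in a RefSeq gene table of another assembly, GRCm38.p6 (21900 genes). That table served only to say which chromosome a gene is on, and none of its coordinates was set against the sites. For each autosome, the number of sites was also predicted from the gene count by a straight line on log scales through the other 18 autosomes. Sites at most 12.5 kb apart were joined, and groups of 10 or more sites are called clusters. The number of clusters was compared with that after the gaps of each chromosome were put in random order 100 times. Sites narrower than 400 bp are called narrow and those wider than 1500 bp wide.

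The density per Mb, spacing and clusters of sites were planned before the data were examined, as were the 10 widest sites and the 5 longest clusters, which are named by rule. The sites per protein-coding gene, the cluster minimum of 10 sites, the width classes, the 1-Mb and 10-Mb windows and the neighbours of narrow sites were chosen after seeing the data. The planned placement of sites at genes, the comparison of 11 lists of genes (B cell identity, p53 targets, Myc targets, Bcl2 family apoptosis regulators, tumour genes of the model, housekeeping genes, T cell, myeloid, erythroid, endothelial and stromal markers, and liver and neuron genes) and the search for 10 sequence motifs need an mm9 annotation or sequence and were not analysed here. Alternatives to the settings were the sites above the median width, covered bases in place of sites, autosomes and X alone, merging of touching sites, and joining distances of 5 and 25 kb. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated data: with 1.6 times as many sites put on 1 of 19 simulated autosomes, the median estimate over 200 simulations was 1.59 and that autosome ranked first in 95% of them. The planted excess was close to that found for chromosome 3, and the scatter of the other simulated autosomes was a fixed setting. No simulation of this measure was run without an excess. The simulations therefore check the calculation and do not say how often such an excess arises without a cause.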

Results

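The DNaseI library of lymphoma T6 gave 53593 accessible sites, which together covered 43.3 Mb of the mm9 genome. Autosomes 1 to 19 held 52741 of them, the X chromosome 756 and the Y chromosome 5. A further 89 lay on contigs without a position on a chromosome and 2 on the mitochondrial chromosome. The purpose stated for this library was to map open chromatin in this tumour, as part of a study of p53-induced regression of Myc-driven lymphomas. The comparisons that 1 list allows are those within the genome of this tumour: between widths, chromosomes and regions. Read counts and depth were not given with the sites, and there was no replicate.

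Most sites were of intermediate width, and narrow ones outnumbered wide ones. The median width was 663 bp (95% interval 658 to 668, 53593 sites), with quartiles of 352 and 1063 bp. Sites of 400 to 1500 bp made up 58.1% of the list (57.7 to 58.6%) and 59.9% of the covered bases. Narrow sites of under 400 bp made up 30.5% of the list (30.1 to 30.9%) but 11.5% of the covered bases. Wide sites of over 1500 bp made up 11.4% of the list (11.1 to 11.7%) and 28.6% of the covered bases. The narrowest width was 249 bp, and 1292 sites (2.41%) had exactly that width, against 178 sites at the next most frequent width of 252 bp.

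The widest site covered 11025 bp of chromosome 12 (114656655 to 114667679), 1.64 times the next widest. Next came a site of 6740 bp on chromosome 7 (107648725 to 107655464), one of 6733 bp on chromosome 8 (87497963 to 87504695) and one of 6662 bp on chromosome 17 (34253770 to 34260431). The mitochondrial chromosome followed with a site of 6565 bp that began at its first base, and its other site spanned 10877 to 16419. Chromosome 8 held another site of 6274 bp (87183611 to 87189884), and chromosome 12 one of 6186 bp (81212130 to 81218315). The list of 10 closed with sites of 6112 bp on chromosome 17 (39979801 to 39985912), 5732 bp on chromosome 15 (61822010 to 61827741) and 5716 bp on chromosome 17 (71198006 to 71203721). The site on chromosome 17 at 39979801 had no other site within the joining distance used for clusters. The site at 34253770 of the same chromosome lay in a cluster of 38. The genes, the repeated sequence and the input signal at these positions were not analysed here, so reads piled up on repeats were not excluded.

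Accessible sites were concentrated in part of the genome. The median gap between neighbouring sites was 7.05 kb (95% interval 6.92 to 7.19), with quartiles of 1.35 and 23.3 kb. Gaps of over 100 kb were 6.12% of all gaps but held 72.1% of the distance between sites. Of 2578 windows of 1 Mb on the autosomes and X, 595 (23.1%) held no site and the median window held 10. The densest 10%, 258 windows with 57 or more sites each, held 38.7% of the sites (38.3 to 39.1%). The densest window was 80 to 81 Mb of chromosome 10, with 186 sites, and its neighbour at 79 to 80 Mb held 156. On chromosome 3, the windows at 87 to 88, 89 to 90 and 95 to 96 Mb held 164, 162 and 134 sites. The windows at 34 to 35 Mb of chromosome 17 and 29 to 30 Mb of chromosome 19 held 137 each. The longest stretch without a site was 15.3 Mb of the X chromosome (110982230 to 126283776), and the longest on an autosome was 10.9 Mb of chromosome 1 (109345081 to 120207311). Stretches of unknown sequence in the assembly were not taken out of these gaps.

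Chromosome 3 stood apart from the other autosomes in the spacing of its sites, and the X chromosome had far fewer sites than any autosome. The median gap on chromosome 3 was 4.92 kb (95% interval 4.55 to 5.44), and those of the 18 other autosomes ran from 6.01 kb on chromosome 7 to 9.28 kb on chromosome 13. Its 4005 sites came to 4.07 per protein-coding gene (3.9 to 4.2). The other autosomes had between 1.76 on chromosome 7 and 3.01 on chromosome 12, with a median of 2.53. The low place of chromosome 7 depended on olfactory, vomeronasal and trace amine receptor genes. Without these families it had 2.22, and the other autosomes ran from 2.14 on chromosome 14 to 3.12 on chromosome 19, against 4.11 on chromosome 3. Against a line through the other autosomes, chromosome 3 had 1.604 times the sites its gene count predicted, and the next highest was chromosome 11 with 1.22 times. The lowest was chromosome 7 with 0.725 times. These predictions counted the receptor genes, and the line was not fitted without them. The same fit with sites and genes both taken per Mb gave 1.525 for chromosome 3 and 1.316 for chromosome 11, again the next highest. By length alone chromosome 3 came after chromosomes 11, 19 and 17, with 25.6 sites per Mb (24.9 to 26.5). The gene-dense chromosome 11 held most, at 37.6 per Mb (36.5 to 38.7), followed by chromosome 19 at 34.5 (33.0 to 36.0) and chromosome 17 at 26.2 (25.2 to 27.3). Chromosome 14 had the lowest autosomal density, at 15.1 per Mb (14.4 to 15.8).

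**Figure D1:**
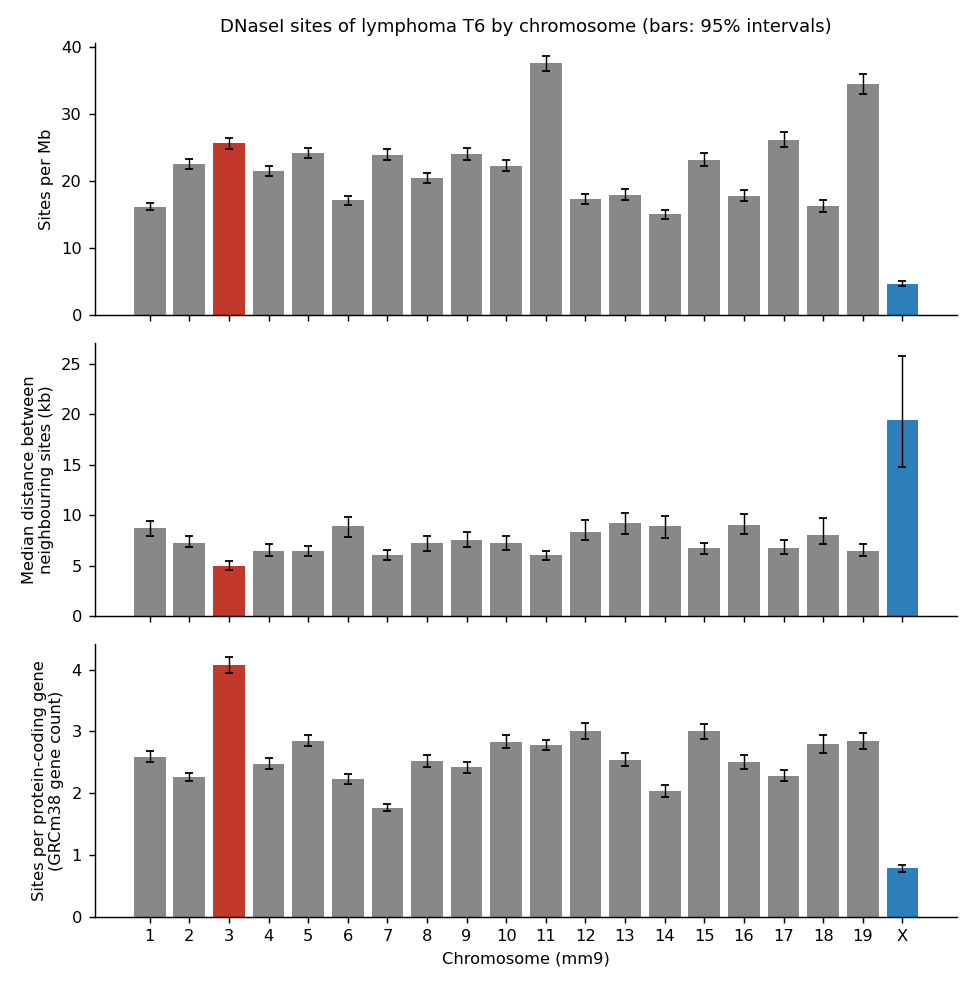
Sites per Mb, median distance between neighbouring sites (kb) and sites per protein-coding gene for each autosome and the X chromosome of lymphoma T6, with chromosome 3 in red, X in blue and 95% counting intervals as error bars. Chromosome 3 has the shortest median distance (4.92 kb) and the most sites per gene (4.07) but comes after chromosomes 11, 19 and 17 in sites per Mb (25.6), and X is lowest in sites per Mb (4.73) and per gene (0.783).

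The widths of the sites on chromosome 3 also differed from those elsewhere. Narrow sites were 35.7% of its list (34.2 to 37.2%), against 28.3 to 31.9% on the other autosomes. Relative to the median of the other autosomes, it had 1.97 times as many sites of 249 to 299 bp per gene (1.83 to 2.11) and 1.83 times as many of 300 to 399 bp (1.69 to 1.97). The ratio was 1.32 for sites of 600 to 999 bp (1.24 to 1.41) and 1.74 for sites wider than 1500 bp (1.59 to 1.90). Wide sites were 12.8% of the sites of chromosome 3 (11.8 to 13.9%), which was second to chromosome 17 at 13% (11.7 to 14.4%), within the counting error of both.

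**Figure D2:**
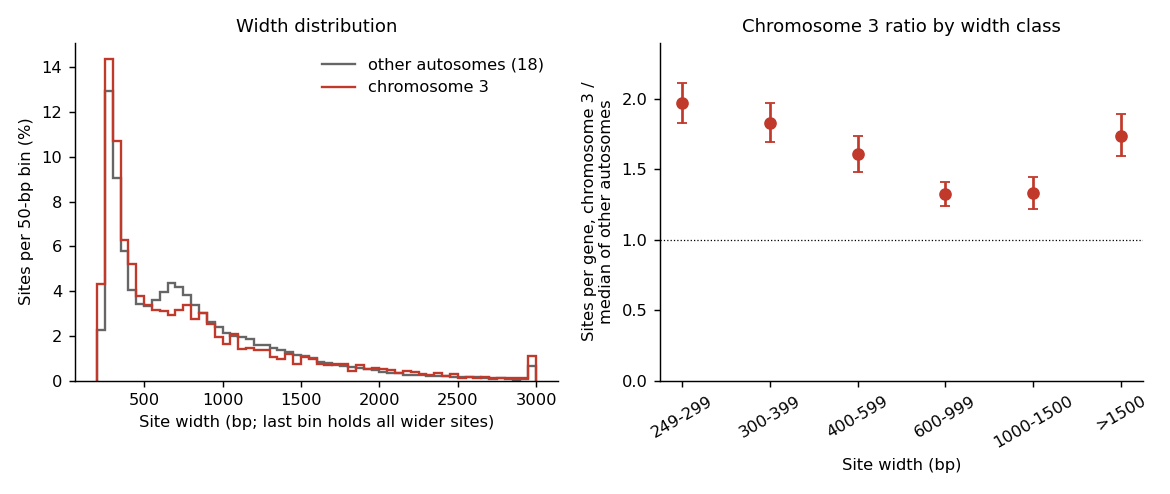
Left, the share of sites in each 50-bp bin of width for chromosome 3 (red) and the 18 other autosomes together (grey). Right, sites per gene of chromosome 3 divided by the median of the other autosomes for 6 classes of width, with 95% counting intervals: the ratio is 1.97 for the narrowest class, 1.32 for 600 to 999 bp and 1.74 above 1500 bp.

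On the X chromosome, the 756 sites came to 4.73 per Mb (4.40 to 5.08) and to 0.783 per protein-coding gene (0.728 to 0.840). These were 0.212 and 0.308 times the medians of the autosomes. The number of X copies in this tumour was not examined, so copy number and accessibility cannot be told apart in these ratios. Of the 161 windows of 1 Mb on X, 47.2% held no site, against 21.5% of the autosomal windows. The median gap on X was 19.4 kb (14.8 to 25.8). The sites that were present had a median width of 672.5 bp, close to the 663 bp of the whole list, and 29.4% of them were narrow (26.1 to 32.8%). The 5 sites on the Y chromosome lay between positions 346410 and 2612737.

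**Figure D3:**
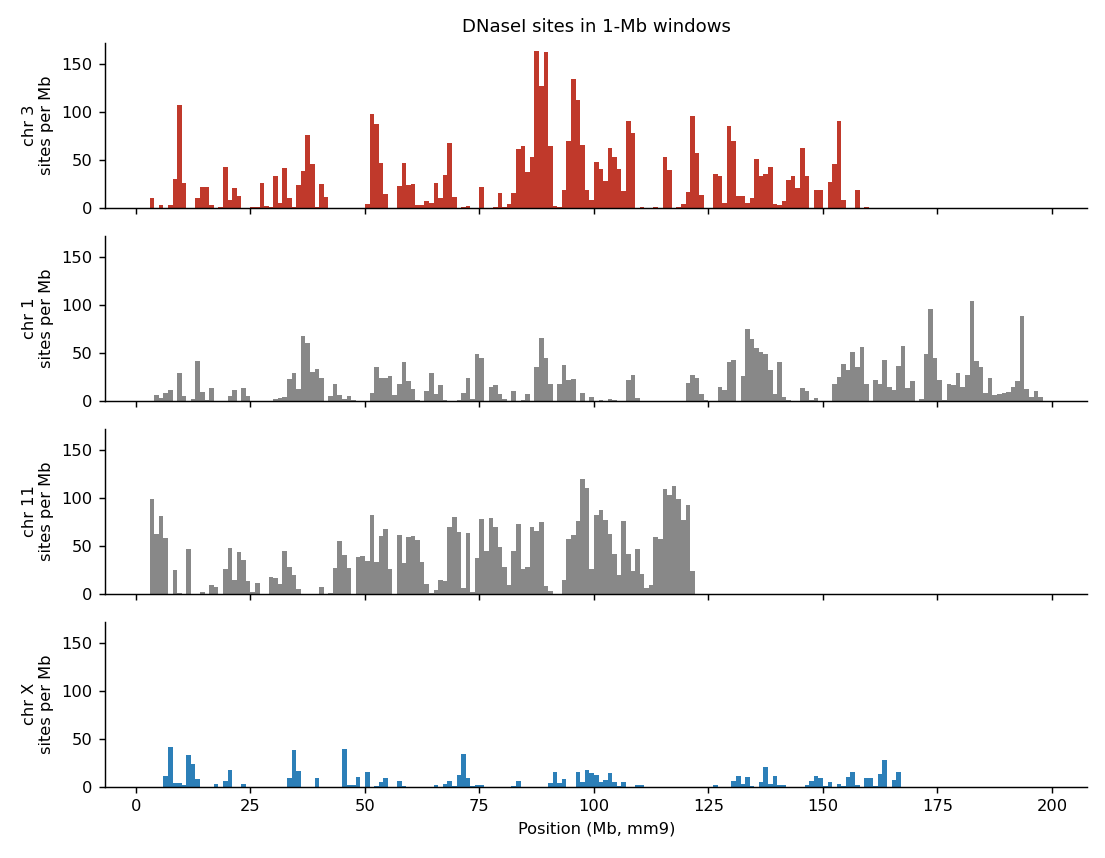
Number of DNaseI sites in each 1-Mb window along chromosomes 3, 1, 11 and X, by mm9 position in Mb and on a common vertical scale. Chromosome 3 has peaks of 164 and 162 sites near 87 to 90 Mb, and X has long stretches without a site, the longest of 15.3 Mb.

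Sites gathered into clusters more often than the lengths of their gaps alone gave. At the main joining distance, 656 clusters of 10 or more sites held 9611 sites (17.9% of the list), and their median length was 51.7 kb. With the gaps of each chromosome in random order there were 292 such clusters on average, and between 250 and 332 over 100 orders. The excess was 2.25 times at this distance, 5.49 times at 5 kb and 1.11 times at 25 kb, where 1270 clusters stood against 1096 to 1201 in random order. Chromosome 3 held 70 clusters with 29.8% of its sites, or 7.12 clusters per 100 protein-coding genes. Chromosome 11 held 73, with 23.4% of its sites and 4.54 per 100 genes, and X held 3.

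The longest cluster ran over 206.4 kb of chromosome 5 (122529930 to 122736306) with 44 sites, of which 7 were wide. It was followed by 178.0 kb of chromosome 7 (71027060 to 71205074) with 35 sites and 176.8 kb of chromosome 2 (169973338 to 170150120) with 41 sites. The remaining 2 of the 5 were both on chromosome 3: 168.4 kb with 33 sites (88887883 to 89056325) and 163.6 kb with 40 sites (95951716 to 96115332). Sites covered 16.2 to 22.2% of the length of these 5 clusters.

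**Figure D4:**
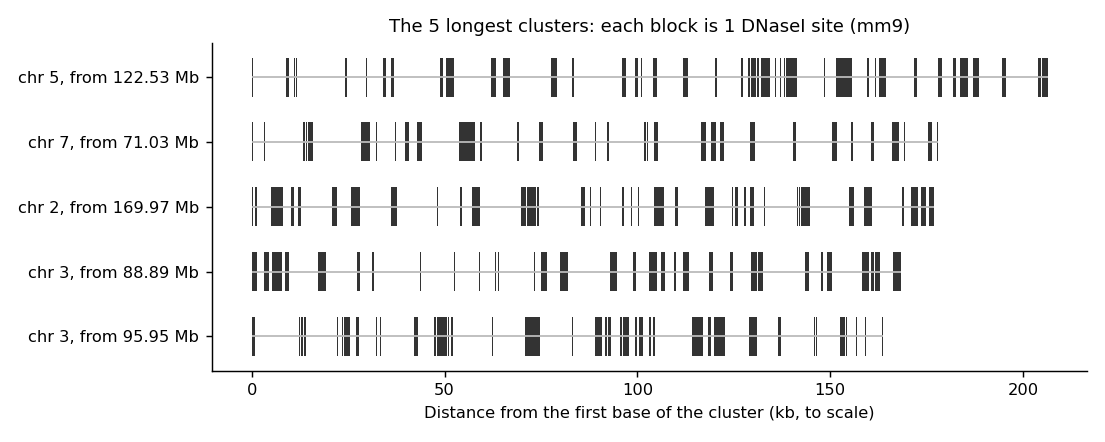
The 5 longest clusters drawn to scale, 1 line per cluster, in kb from the first base of each, with every DNaseI site as a block. The cluster on chromosome 5 is 206.4 kb long and has 44 sites, and 2 of the 5 clusters are on chromosome 3.

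Narrow sites lay close to other sites more often than wider ones. A neighbour within 500 bp was present for 40.6% of narrow sites (39.8 to 41.4%, 16328 sites) and for 27.4% of the rest (27.0 to 27.9%, 37265 sites). The change came between width classes: the share was 39.1% at 400 to 599 bp (38.1 to 40.2%) and 24.3% at 600 to 999 bp (23.6 to 25%). The shortest gap in the list was 52 bp.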

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

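Beside the assembled chromosomes, 89 sites lay on 7 pooled sets of contigs that mm9 gives no position, which the comparisons of chromosomes did not use. They were looked at for that reason alone, and there was no control list to set them against. The set assigned to no chromosome held 34 of them and the set assigned to chromosome 1 held 22. Their median width was 476 bp, against 663 bp for the whole list.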

How the results depend on the processing

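Of 36 recomputed values, 18 stayed within the counting error of the main value, or within 1.5 times of it for a count, 18 moved by more, and none reversed. For the excess of clusters, the range over the random orders took the place of counting error. Some outcomes were set by the change itself, such as the number and median width of the wider sites. Numbers, widths and gaps have no direction to reverse. These counts are therefore no measure of how robust the results are. No wider sampling error could be measured, since there was 1 library. Merging touching sites changed nothing, because none touch. Taking only the sites above the median width, the nearest substitute for a stricter threshold, left 26773 sites with a median width of 1063 bp and a median gap of 15.8 kb. Among these wider sites, the density of chromosome 3 relative to the median of the other autosomes was 1.07 per Mb (1.17 with all sites) and 1.43 per gene (1.61 with all sites), and that of chromosome 11 was 1.79 per Mb (1.71 with all sites). The ratio per gene for chromosome 3 was 1.52 without receptor gene families and 1.54 with sites at most 1 kb apart joined, and chromosome 11 stood at 1.77 times the median by covered bases per Mb. There were 109 clusters at a joining distance of 5 kb, 1270 at 25 kb and 98 among the wider sites. Their excess over random order was 5.49, 1.11 and 7.99 times, so that the size of the excess depends on the joining distance and the width limit. The densest 10% of windows held 30.1% of sites with 5-Mb windows and 41.6% with the wider sites, and 47.2% of narrow sites had a neighbour within 1 kb. Density by mm9 chromosome length, the placement of sites at genes, the gene lists and the motifs were not run. The ratios per gene, the windows and the neighbours, with all their settings, and the joining of sites at most 1 kb apart were chosen after seeing the data. Without counts per site, a stricter threshold by signal could not be tried.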

Other observations

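The tests in this part were chosen after the results were seen. The cluster with the most sites, 49 in 80.3 kb at the start of chromosome 11 (3023043 to 3103363), was also the most densely covered. Sites took up 59.9% of its length, against a median of 21.7% over the 656 clusters and 55.0% in the next highest. Its median gap was 0.545 kb. Repeated sequence and the input library were not examined there, so reads piled up on repeats cannot be told apart from open chromatin. The widest site of the list lies on chromosome 12 and the ninth widest on chromosome 15, the chromosomes that carry Igh and Myc in the gene table. The Eμ-myc transgene joins the Igh enhancer to Myc. Whether either site lies in these genes, and how many copies of the transgene this tumour had, was not tested. On the mitochondrial chromosome, the listed widths of the site of 6565 bp and its neighbour came to 12108 bp together. Lengths of the mm9 chromosomes were not used here, so it was not checked that the listed end at 16419 lies within that chromosome.

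Chromosome 3 held 1.604 times the sites that its gene count predicted, or 1.525 times with sites and genes both taken per Mb. Splitting of single regions is not the whole cause, since with sites at most 1 kb apart joined it still had 3.08 regions per gene (2.97 to 3.19) and the highest other autosome 2.35, nor are olfactory, vomeronasal and trace amine receptor families, without which it had 4.11 sites per gene (3.99 to 4.24) against at most 3.12 elsewhere. A candidate explanation is more DNA of chromosome 3 in this tumour, so that weaker sites pass one common threshold: narrow sites were 35.7% there (34.2 to 37.2%), against at most 31.9% on the 18 other autosomes, and exceeded the 30.04% of these autosomes in 14 of 16 windows of 10 Mb, but also in 11 of 13 on chromosome 10 and 6 of 7 on chromosome 19. Sites over 1500 bp were in excess too, at 1.74 times the other autosomes per gene (1.59 to 1.90) against 1.32 times for 600 to 999 bp, and how width responds to copy number was not tested. The count of windows could not decide. Even all 16 above 30.04% would have stayed within counting error of the shares of chromosomes 10 and 19. Over the whole chromosome, the share of narrow sites did lie above that of every other autosome. The explanation stays open, since reads of the input library were not analysed here, and regulation of genes on chromosome 3 was not tested.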
